A study of Homo sapiens with 9 samples.

How the data were processed

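AC16 cells are a proliferating human line made by fusing cells of adult ventricular heart muscle with SV40-transformed fibroblasts. There were 3 groups of 3 samples. Vehicle cells had 0.1% DMSO over 72 h, and treated cells had CDDO-Me at 100 nM over either 24 h or 72 h. CDDO-Me (bardoxolone methyl) is a synthetic triterpenoid that binds KEAP1, the adaptor that marks the transcription factor NRF2 for degradation. Polyadenylated RNA was made into libraries with the TruSeq RNA v2 kit, which does not keep the strand, per the labels' protocols. Titles and the design text use CDDO in places where the treatment label gives CDDO-Me, and all treated samples were taken as CDDO-Me. Groups and replicate numbers came from the labels. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

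The authors deposited a table of whole-number read counts per Ensembl gene, summed over exons, with no normalization. The submitters' processing notes name STAR, SAMtools, Subread and featureCounts and the builds hg38 and GRCh38, with no versions. The annotation release and the settings for strand and for reads that match several places are not given in the sources used here. The table lists 58299 genes, with no mitochondrial gene and no entry that names no gene. Every one of the 9 columns was matched to a sample by its name. Of the gene IDs, 57717 were found in a table of gene names and 58179 in GENCODE 29, where 57438 had the same start and end. GENCODE 29 was used for gene types, and coordinates are those of the deposited table (GRCh38). Because the kit does not mark strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may be split or lost.

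Total counts ran from 16898977 to 27910031 per library. At these depths 3 counts equal 0.107 to 0.178 CPM (read counts scaled to a common library total), which is the limit that a count of 0 allows, and that limit covers counting error only. No pair of columns was identical. The counts of each pair of replicates differed by more than sampling noise (chi-square over degrees of freedom of at least 2.09).

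The count test was edgeR 4.0.16 (quasi-likelihood, robust, trimmed mean of M values for library size, filterByExpr) in R 4.3.3, with all 9 libraries in 1 fit of 3 group means and 6 residual degrees of freedom. This left 14965 genes, which held 99.87 to 99.9% of counts in each library. The common biological coefficient of variation was 11.5%. P-values were adjusted by Benjamini and Hochberg over the tested genes, and a gene was called past an adjusted p of 0.05. Values are CPM after library size scaling, as mean ± SD of 3 libraries, and log2 fold changes with a standard error (SE). This SE was derived from the test, as the size of the log2 fold change over the square root of its F statistic. The ratio of fold change to SE need not rank genes as the adjusted p does. Of 41 gene lists, 40 had tested members. They were tested with camera in limma 3.58.1 (preset correlation 0.01), and p-values were adjusted over the lists of a comparison. Lists were also tested with an estimated correlation and with fry. The NRF2 target list joins 6 of these lists, which leaves 39 others.

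The groups, tests, lists, gene rule and most of the alternatives were fixed before the data were examined. The rule names 7 genes of the pathway, up to 6 genes with the highest and 6 with the lowest log2 fold change past the threshold (average log2 CPM of at least 3, groups fully apart), and up to 4 members per list with the smallest adjusted p, plus the strongest member in the opposite direction, or the most expressed member where none passed. A few genes that the rule named are not reported singly, and the counts of named genes leave them out. Full separation of 3 against 3 libraries has a chance of 10% for a gene with no change. A score of retained RNA, the median log2 CPM of 16 transcripts known for nuclear retention or detained introns, was defined after the libraries had been compared.

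The test was tried on simulated data made from the real means and library sizes with 200 changed genes. For 24 h against DMSO it recovered 94% of genes raised 2-fold and 74% of those raised 1.5-fold, with 15 false calls of 188. For 72 h against DMSO the shares were 88% and 64%, with 10 false calls of 172. For 72 h against 24 h they were 90% and 70%, with 17 of 183. Of genes lowered 2-fold it recovered 82%, 74% and 74% in these comparisons, in the same order. Each gene had 1 dispersion in all libraries, so the simulation held no library that differs from its group more than others do. Random lists of 20 genes, drawn from the unchanged genes of these simulated data, gave a camera p under 0.05 in 0.5% of 200 draws in each comparison. Genes were simulated independently of each other, so this cannot show how camera behaves on lists of correlated genes.

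Alternatives were other library size factors, no filter or a stricter one (CPM of 1 in 3 libraries), DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, and leaving out each replicate. Added after seeing the data were leaving out libraries of the third group, leaving out both libraries that stood apart, the retained-RNA score or a split of the libraries as a term, sample weights, and removal of each library's trend with gene length. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No gene was left out of the tests other than by the filter.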

Results

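RNA from AC16 cells was counted in 9 libraries: 3 after 72 h with vehicle (DMSO), 3 after 24 h and 3 after 72 h with 100 nM CDDO-Me. Total counts were 19382833 to 20570568 in the DMSO group, 16898977 to 27910031 at 24 h and 18801683 to 20704953 at 72 h. By its title the series concerns NRF2 activation by CDDO-Me and protection of these cells from doxorubicin, and no library received doxorubicin. The comparisons are treated against vehicle at each time, and 72 h against 24 h of treatment. No vehicle library of 24 h was analysed here, so the 24 h group differs from DMSO in culture time as well as in treatment. Gene p-values below are adjusted p-values of edgeR's quasi-likelihood test, list p-values are adjusted p-values of camera, and values after ± beside a log2 fold change are SE.

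The 3 CDDO-Me 72 h libraries lay close together, with a biological coefficient of variation of 2.7 to 3.3% between pairs. CDDO-Me 24 h replicate 3 stood apart from replicates 1 and 2 (19.9 and 20.9%, against 6.4% between these), and lay nearer to the 72 h libraries (12.8 to 13.5%). DMSO replicate 1 stood apart less (12.1 and 13.8%, against 7.8% between replicates 2 and 3). The retained-RNA score was above the mean in DMSO replicate 1 (0.20), and in CDDO-Me 24 h replicates 1 (0.14) and 2 (0.38), and below it in the other 6 libraries (−0.02 to −0.21). The RNA quality list, nuclear-retained and histone RNAs with 5 tested members, had a median of −0.47 in CDDO-Me 24 h replicate 3, relative to the DMSO mean, against 0.61 and 0.44 in replicates 1 and 2, 0.29 to 0.57 at 72 h and −0.08 to 0.12 in DMSO. All 9 libraries entered the estimate of spread in each test.

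**Figure D1:**
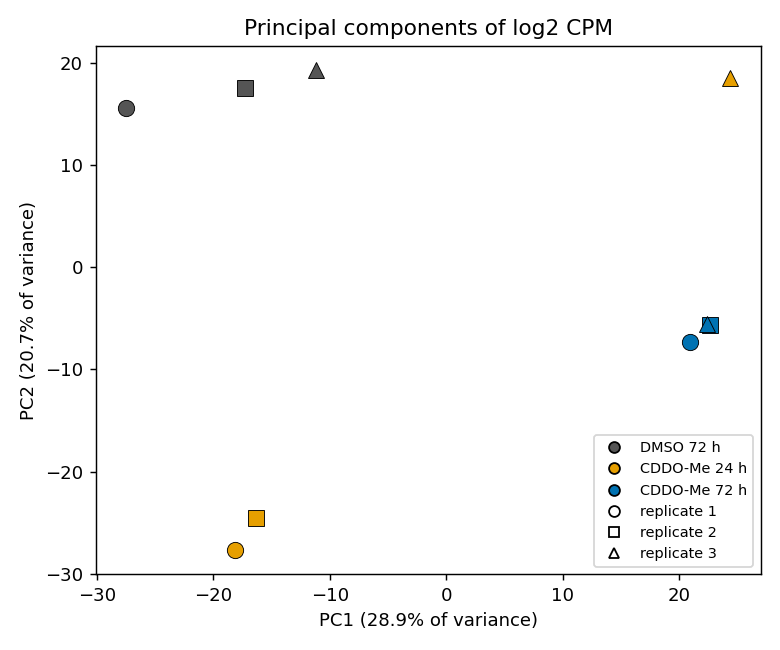
Principal components of log2 CPM, with component 1 (28.9% of variance) on the x axis and component 2 (20.7%) on the y axis; each point is a library, coloured by group and shaped by replicate number. The 72 h libraries lie together, and CDDO-Me 24 h replicate 3 lies away from replicates 1 and 2.

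NQO1, a quinone reductase gene and a standard NRF2 target (ENSG00000181019, chromosome 16, 69706996 to 69726951), stood at 449.2 ± 40.3 CPM (SD, n = 3) in DMSO, 1879.1 ± 255.9 at 24 h and 3348.5 ± 40.5 at 72 h. HMOX1, which encodes heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), stood at 23.8 ± 1.84, 312.1 ± 288 and 816.4 ± 66.7 CPM. Its 24 h libraries held 145.8, 145.8 and 644.6 CPM, the last in replicate 3. GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, went from 118.4 ± 4.63 to 340.8 ± 174.6 and 456.4 ± 7.76 CPM. TXNRD1, thioredoxin reductase 1, went from 664.8 ± 94.9 to 1916.9 ± 1079.4 and 2271.8 ± 71.8 CPM. SRXN1, sulfiredoxin, was at 7.61 ± 2.89, 24.8 ± 15.7 and 28.9 ± 1.32 CPM. The transcripts of the regulator pair did not pass in any comparison: NFE2L2, the gene of NRF2, was at 103.3 ± 6.38, 99.9 ± 7.85 and 108.2 ± 3.8 CPM, and KEAP1 at 118.5 ± 6.18, 141.9 ± 21.7 and 146.4 ± 4.13 CPM. Their log2 fold changes were −0.05 ± 0.08 and 0.26 ± 0.10 at 24 h, and 0.07 ± 0.08 and 0.30 ± 0.10 at 72 h (adjusted p from 0.0806 to 0.864). Without CDDO-Me 24 h replicate 3, KEAP1 passed at 72 h (adjusted p 0.00317).

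**Figure D2:**
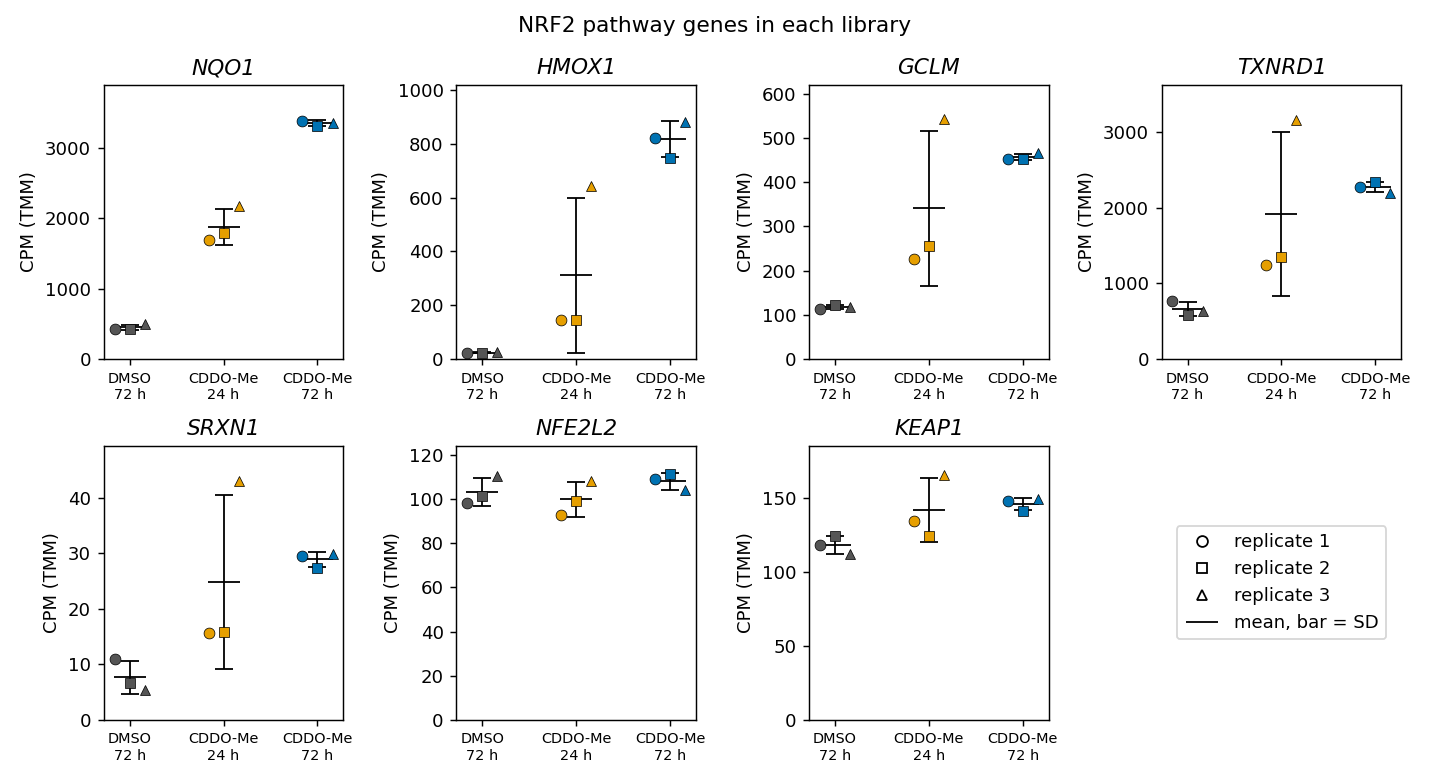
CPM after library size scaling (y axis, linear, from 0) of 7 NRF2 pathway genes in the 3 groups (x axis); points are libraries, shaped by replicate number, and bars are the mean with SD of 3 libraries. NQO1 goes from 449.2 to 3348.5 CPM, and CDDO-Me 24 h replicate 3 lies above replicates 1 and 2 for HMOX1, GCLM, TXNRD1 and SRXN1.

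After 24 h of CDDO-Me, NRF2 target genes were higher than in DMSO, and EDN1 and 4 of 15 immediate early genes were lower. TRIM16L rose by 3.15 ± 0.23 (log2), NQO1 by 2.06 ± 0.10 (4.18-fold, adjusted p 9.52e-08), TRIM16 by 2.02 ± 0.23 and the efflux pump gene ABCC3 by 1.64 ± 0.17. TRIM16 and TRIM16L are close copies, so their counts may share reads. SLC7A11, the cystine transporter, and AKR1C1, an aldo-keto reductase with close paralogs, were at 2.51 ± 0.43 and 2.27 ± 0.38 (adjusted p 0.0353 and 0.0309). Both calls ended without any 1 of the DMSO or the 72 h libraries, at adjusted p of up to 0.125 and 0.116. Without CDDO-Me 24 h replicate 3 both passed with lower folds, at 1.84 and 1.68 (adjusted p 2.8e-10 and 3.5e-09). EDN1, the gene of the vasoconstrictor endothelin 1, had the lowest log2 fold change of the named genes (−2.92 ± 0.24, from 39.2 ± 13.8 to 5.17 ± 0.539 CPM, adjusted p 7.96e-05). DUSP1, a phosphatase of MAP kinases, was at −1.84 ± 0.16, the receptor gene GPRC5A at −1.52 ± 0.14, DIO2, a deiodinase that activates thyroid hormone, at −1.52 ± 0.15 and RASGRP3 at −1.42 ± 0.17. OXTR, the oxytocin receptor gene, was at −1.29 ± 0.23 (adjusted p 0.0240), and this call ended without any 1 of the 24 h libraries (up to 0.0791) or without CDDO-Me 72 h replicate 3 (0.0503). HMOX1 (3.71 ± 0.68), GCLM (1.53 ± 0.31), TXNRD1 (1.53 ± 0.35) and SRXN1 (1.72 ± 0.46) did not pass at 24 h, with adjusted p of 0.0557, 0.0667, 0.0981 and 0.143. Without CDDO-Me 24 h replicate 3 all 4 passed, with lower folds (2.61, 1.02, 0.96 and 1.05; adjusted p 3.44e-13, 2.10e-08, 2.84e-06 and 0.00628). HMOX1 also passed without replicate 2 (0.0491) and GCLM without replicate 1 (0.0323).

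Of 49 tested NRF2 targets, 25 rose at 24 h (37 adjusted over the list alone), with a median of 0.75. No member fell by edgeR, DESeq2 or limma-voom, or at an unadjusted p under 0.05 (camera 2.94e-74, adjusted p 0.00753 with an estimated correlation). The list's median was 0.60 and 0.67 in replicates 1 and 2 and 0.99 in replicate 3. In the quinone and carbonyl detoxification list 9 of 13 rose (median 1.19), among them the epoxide hydrolase gene EPHX1 (1.19 ± 0.10) and PIR (1.59 ± 0.14). In the heme and iron list 5 of 9 rose (median 1.07), with both ferritin chains, FTL (1.29 ± 0.14) and FTH1 (1.5 ± 0.21), and the heme transporter gene SLC48A1 (1.12 ± 0.14). Ferritin genes have processed copies that can take reads. In the NADPH list 5 of 6 rose, with TKT (0.86 ± 0.07) of the pentose phosphate pathway and the malic enzyme gene ME1 (0.61 ± 0.10). Glutathione genes rose in 3 of 10 (MGST1 1.08 ± 0.15, GSTM3 0.71 ± 0.11, and SLC7A11) and efflux pumps in 2 of 6 (ABCC3, and ABCC2 at 1.77 ± 0.27). In the thioredoxin list 1 of 5 rose, TXN (0.53 ± 0.12, adjusted p 0.0328), and the list's adjusted p was 0.155 with an estimated correlation. Among 14 regulators of the pathway, a list apart from the 49 targets, 4 rose, with MAFG (0.70 ± 0.10), the gene of a small partner protein of NRF2. That list's adjusted p was 0.113 with an estimated correlation. Adjusted over the list alone, 11 detoxification, 7 heme and iron, 5 NADPH, 8 glutathione, 2 efflux, 4 thioredoxin and 6 regulator genes rose. Without DMSO replicate 2, 13 NRF2 targets, 3 detoxification, 3 heme and iron and 3 NADPH genes passed. The last count was 3 without DMSO replicate 3 too, and 3 heme and iron genes passed without DMSO replicate 1. The call of TXN ended when any library other than CDDO-Me 24 h replicates 1 and 3 was left out (adjusted p up to 0.193). Without replicate 3 of that group, 3 thioredoxin and 6 glutathione genes passed.

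Other lists also differed at 24 h. In the ATF4 and integrated stress response list 5 of 20 rose (12 adjusted over the list alone; median 0.34, camera 6.25e-13, adjusted p 0.00753 with an estimated correlation), with the transcription factor gene CEBPB (0.81 ± 0.08) and SESN2 (0.52 ± 0.08). Without CDDO-Me 24 h replicate 3, 12 rose and 1 was lower. The count was 3 without DMSO replicate 1 or CDDO-Me 72 h replicates 1 or 2, and 2 without DMSO replicate 2, CDDO-Me 24 h replicates 1 or 2 or CDDO-Me 72 h replicate 3. In the list of doxorubicin targets, transport and metabolism 4 of 16 rose (5 adjusted over the list alone; median 0.13, camera 1.67e-08): NQO1, ABCC2, POR (0.49 ± 0.07), a reductase that can reduce doxorubicin, and CBR1 (0.42 ± 0.08), a carbonyl reductase that converts it to its alcohol. NQO1, ABCC2 and CBR1 are NRF2 list members too, and the call of CBR1 ended without DMSO replicate 2 (adjusted p 0.0582). In the immediate early list 4 of 15 fell (9 adjusted over the list alone, with 1 higher; median −0.62, camera 1.85e-13, adjusted p 0.0467 with an estimated correlation): DUSP1, JUN (−0.75 ± 0.11), IER3 (−0.54 ± 0.10) and IER2 (−0.62 ± 0.12). The call of IER2 ended without DMSO replicates 2 (0.0951) or 3 (0.0536) or CDDO-Me 24 h replicate 2 (0.0586), and 9 members passed without DMSO replicate 1 and 7 without CDDO-Me 24 h replicate 3. The list's median per library, relative to the DMSO mean, was −0.52 to −0.71 at 24 h, and −0.27 in DMSO replicate 1, against 0.12 and 0.18 in DMSO replicates 2 and 3. In the TGF-beta and YAP list 3 of 14 fell (6 adjusted over the list alone; median −0.54, camera 3.64e-13, adjusted p 0.0338 with an estimated correlation): CCN1, a matricellular protein gene (−0.94 ± 0.08), SKIL (−0.61 ± 0.11; adjusted p 0.0625 without DMSO replicate 2) and ACTA2 (−1.24 ± 0.24). The list's median per library was −0.60 and −0.65 in replicates 1 and 2 and −0.07 in replicate 3, and without that replicate 9 members fell. Among 7 smooth muscle markers 1 fell, MYOCD, the gene of a coactivator that drives smooth muscle genes (−1.85 ± 0.22; list median −0.32, camera 1.09e-05). Adjusted over the list alone 4 fell, and 2 did without CDDO-Me 24 h replicates 1 or 3.

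Over all genes, 145 were higher and 176 lower at 24 h than in DMSO, with 49 and 25 of these at least 2-fold (197 in all without CDDO-Me 24 h replicate 3). The total of 321 fell to 134 without DMSO replicate 2 and 206 without CDDO-Me 24 h replicate 2, and was 1657 without CDDO-Me 24 h replicate 3, 3464 without both libraries that stood apart, and 100 with the 72 h libraries left out of the fit.

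**Figure D3:**
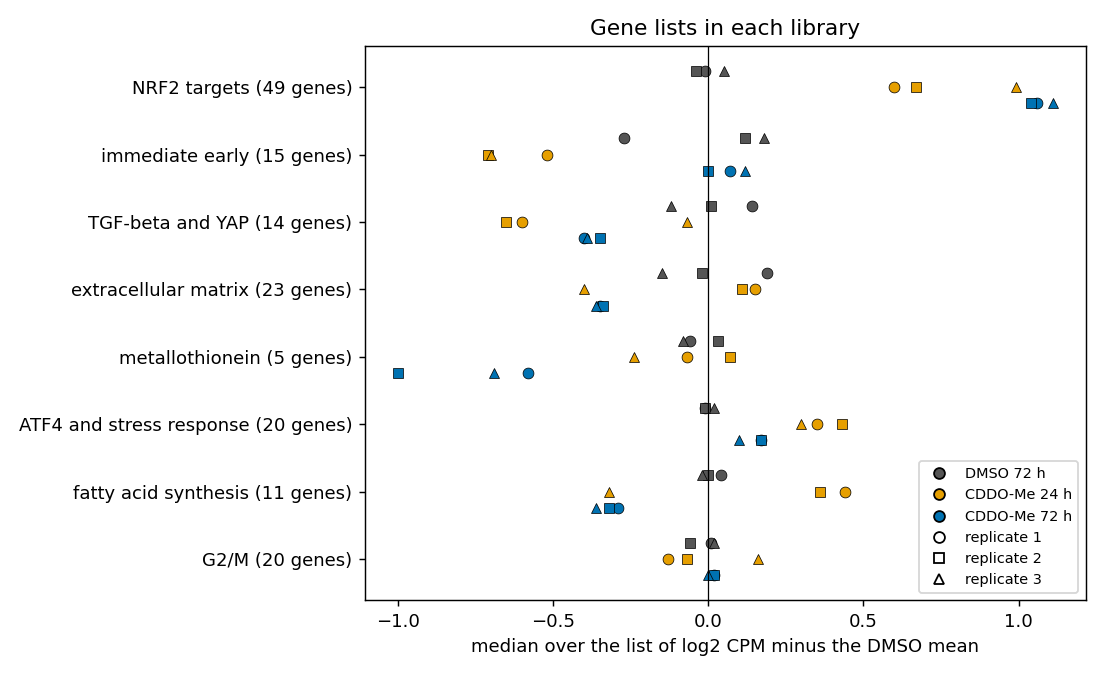
Median over each of 8 gene lists of log2 CPM minus the DMSO mean (x axis) in each library; colours are groups and shapes are replicate numbers. The NRF2 target list lies at 0.60 to 0.99 at 24 h and 1.04 to 1.11 at 72 h, and the immediate early list at −0.52 to −0.71 at 24 h, 0 to 0.12 at 72 h and −0.27 in DMSO replicate 1, against 0.12 and 0.18 in the other DMSO libraries.

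After 72 h of CDDO-Me, against vehicle of the same time, NRF2 targets were higher, and POSTN, the metallothionein genes MT2A and MT1E and the smooth muscle genes ACTG2 and MYOCD were lower. HMOX1 rose by 5.10 ± 0.72 (34.2-fold, adjusted p 0.0106), TRIM16L by 3.63 ± 0.23, AKR1C1 by 3.41 ± 0.39, SLC7A11 by 2.91 ± 0.43 and NQO1 by 2.90 ± 0.11 (7.45-fold, 1.26e-09). HKDC1, a hexokinase family gene, was at 3.29 ± 0.72 (0.0460), a call that ended without any 1 of the DMSO or 72 h libraries (up to 0.137). POSTN, the gene of the matrix protein periostin, had the lowest log2 fold change of the named genes (−3.33 ± 0.18, from 41.7 ± 5.07 to 4.13 ± 0.448 CPM, adjusted p 1.17e-07). ACTG2, a smooth muscle actin gene, was at −1.97 ± 0.30 and the basement membrane gene TINAGL1 at −1.92 ± 0.32. CEMIP (−2.15 ± 0.36, adjusted p 0.0151), which degrades hyaluronan, and LTBP3 (−2.02 ± 0.34, 0.0135), which binds latent TGF-beta, were lost without any 1 of the 72 h libraries (up to 0.0752 and 0.0709). GPRC5B (−2.43 ± 0.51, 0.0383) was lost without any 1 of 7 libraries, all but CDDO-Me 24 h replicates 2 and 3 (up to 0.156). GCLM was at 1.95 ± 0.32 (0.0139; up to 0.0552 without DMSO replicate 1 or any 1 of the 72 h libraries) and TXNRD1 at 1.77 ± 0.36 (0.0320; up to 0.111 without any 1 of the DMSO or 72 h libraries). SRXN1 was at 1.93 ± 0.46 and did not pass (0.0564). It passed without CDDO-Me 24 h replicates 2 (0.0379) or 3 (1.07e-05). CDDO-Me 24 h replicate 3 is outside this comparison but enters its estimate of spread. Without that library HKDC1, CEMIP, LTBP3 and GPRC5B passed with adjusted p of 8.35e-11, 1.44e-14, 1.53e-11 and 1.32e-09. GCLM and TXNRD1 then passed with 1.2e-13 and 1.7e-10.

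At 72 h 37 of the 49 NRF2 targets rose (40 adjusted over the list alone), with a median of 1.05 (camera 2.76e-103, adjusted p 0.00384 with an estimated correlation). No member fell by edgeR, DESeq2 or limma-voom, and 1 was lower at an unadjusted p under 0.05 and by limma-voom with sample weights. Detoxification genes rose in 11 of 13 (median 1.88), with EPHX1 and PIR both at 1.88, and the aldose reductase gene AKR1B1 at 1.01 ± 0.09. Heme and iron genes rose in 8 of 9, with FTL at 2.28 ± 0.14 (8348.1 ± 113.6 CPM against 1722.4 ± 148.4), FTH1 at 2.23 ± 0.21, SLC48A1 at 1.59 ± 0.14 and BLVRB, a biliverdin reductase gene, at 0.68 ± 0.09. NADPH genes rose in 5 of 6, with PGD at 1.5 ± 0.18, TKT at 1.05 ± 0.07 and ME1 at 0.87 ± 0.10. Glutathione genes rose in 8 of 10, with MGST1 at 1.46 ± 0.16 and GSTM3 at 1.42 ± 0.11, and the count was 5 without DMSO replicate 1, 4 without DMSO replicate 2 or CDDO-Me 72 h replicates 1 or 2, and 3 without CDDO-Me 72 h replicate 3. Thioredoxin genes rose in 3 of 5, TXN (0.97 ± 0.12), PRDX1 (0.63 ± 0.11) and TXNRD1, where the list's adjusted p was 0.104 with an estimated correlation. Efflux pumps rose in 2 of 6 (ABCC3 1.92 ± 0.17, ABCC2 1.56 ± 0.27). Among 14 regulators 4 rose, TRIM16L, TRIM16 (2.56 ± 0.23), MAFG (0.77 ± 0.10) and SQSTM1 (1.08 ± 0.19), where the list's adjusted p was 0.0996 with an estimated correlation. Adjusted over the list alone, 12 detoxification, 9 heme and iron, 5 NADPH, 9 glutathione, 4 thioredoxin, 2 efflux and 6 regulator genes rose, and 1 thioredoxin gene was lower.

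Metallothioneins, small proteins that bind zinc and copper, fell at 72 h in 2 of 5 (4 adjusted over the list alone; median −0.76, camera 3.68e-09, adjusted p 0.00495 with an estimated correlation): MT2A (−1.62 ± 0.10, from 456.4 ± 71.6 to 148.9 ± 1.93 CPM) and MT1E (−0.76 ± 0.10). These genes are close paralogs, so reads may be split between them. Extracellular matrix genes fell in 6 of 23 (10 adjusted over the list alone, with 1 higher; median −0.35, camera 1.23e-06, adjusted p 0.251 with an estimated correlation), with the protease inhibitor TIMP3 (−1.16 ± 0.11), the collagen cross-linker LOX (−0.70 ± 0.11), fibrillin FBN1 (−0.58 ± 0.10) and fibronectin FN1 (−0.87 ± 0.16). The counts were 11 lower and 2 higher without CDDO-Me 24 h replicate 3. Fibroblast markers fell in 3 of 11 (3 adjusted over the list alone; median −0.09, mean −0.54, camera 2.38e-05, adjusted p 0.131 with an estimated correlation), POSTN, FAP (−1.28 ± 0.28) and PDGFRA (−0.76 ± 0.19). The calls of FAP and PDGFRA ended without any 1 of the DMSO or 72 h libraries (up to 0.133 and 0.154). Without CDDO-Me 24 h replicate 3 both held (adjusted p 2.69e-08 and 1.47e-05). TGF-beta and YAP genes fell in 3 of 14 (4 adjusted over the list alone; median −0.42, camera 1.84e-05, adjusted p 0.131 with an estimated correlation), with TGFBI (−1.42 ± 0.14) and SKIL (−1.05 ± 0.11). The NF-kappaB and inflammation list fell in 5 of 17 (7 adjusted over the list alone; camera 5.77e-05, adjusted p 0.104 with an estimated correlation), with the cytokine genes LIF (−1.13 ± 0.15) and IL1B (−1.72 ± 0.27). The count was 2 without DMSO replicates 1 or 2 or CDDO-Me 72 h replicates 2 or 3, and 3 without DMSO replicate 3 or CDDO-Me 72 h replicate 1. Of 7 smooth muscle markers (camera 0.00108, adjusted p 0.0401 with an estimated correlation) 2 were lower, MYOCD (−2.63 ± 0.23) and MYLK (−0.66 ± 0.10), and 1 was higher, CNN1 (0.37 ± 0.10, adjusted p 0.04995), a call lost without any 1 of the DMSO or 72 h libraries (up to 0.190). Epithelial keratins KRT19 (−1.49 ± 0.15) and KRT18 (−1.0 ± 0.12) fell, 2 of 5 epithelial markers (3 adjusted over the list alone; camera 4.52e-05, adjusted p 0.0377 with an estimated correlation). In the p53 list 3 of 16 rose (6 adjusted over the list alone; median 0.13, camera 0.00117, adjusted p 0.0395 with an estimated correlation), with the cell cycle inhibitor CDKN1A (0.69 ± 0.07) and TP53I3 (0.74 ± 0.10). In the doxorubicin list 5 of 16 rose, with NQO1, ABCC2, POR (0.71 ± 0.07) and CBR1 (0.61 ± 0.08), and 1 fell, RAC2 (−0.41 ± 0.09, adjusted p 0.0125; up to 0.0843 without any 1 of the 72 h libraries). The immediate early list had 1 gene higher, KLF2 (0.79 ± 0.16), and a median of −0.06 (mean 0.08, camera 0.299). Without DMSO replicate 1, 1 gene was higher and 1 lower, without DMSO replicate 3, 2 were higher, and without CDDO-Me 24 h replicate 3, 2 were higher and 1 lower.

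Over all genes, 432 were higher and 469 lower at 72 h than in DMSO, with 124 and 97 at least 2-fold (147 in all without CDDO-Me 72 h replicate 1). The total of 901 was 481 without DMSO replicate 2, 401, 422 and 401 without CDDO-Me 72 h replicates 1, 2 and 3, 1972 without CDDO-Me 24 h replicate 3, and 2724 without both libraries that stood apart. It was 1776 with the 24 h libraries left out of the fit.

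The calls at both times against the same DMSO libraries overlapped. Of the genes higher at 24 h, 119 (82.1%) were higher at 72 h too, and of those lower 122 (69.3%) were lower, where independent lists would share 4.19 and 5.52. No gene was called in opposite directions by edgeR, 1 was by DESeq2, and 16 of 1040 with an unadjusted p under 0.05 at both times were. The log2 fold changes over 14965 genes correlated at 0.639 (covariance 0.0946), where simulated unchanged groups against the same controls gave 0.502 (0.0343). The 50 simulations gave 0.04 shared calls on average. With no gene changed almost none is called, so that value cannot show what shared controls add to the 241 shared calls. Genes are not independent replicates. The 3 control libraries are too few to be divided into separate sets of 2, so part of the excess may come from the shared controls. The shared total of 241 was 104 without DMSO replicate 2, 150, 157 and 152 without CDDO-Me 72 h replicates 1, 2 and 3, and 615 without CDDO-Me 24 h replicate 3, when 49 genes were called in opposite directions.

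**Figure D4:**
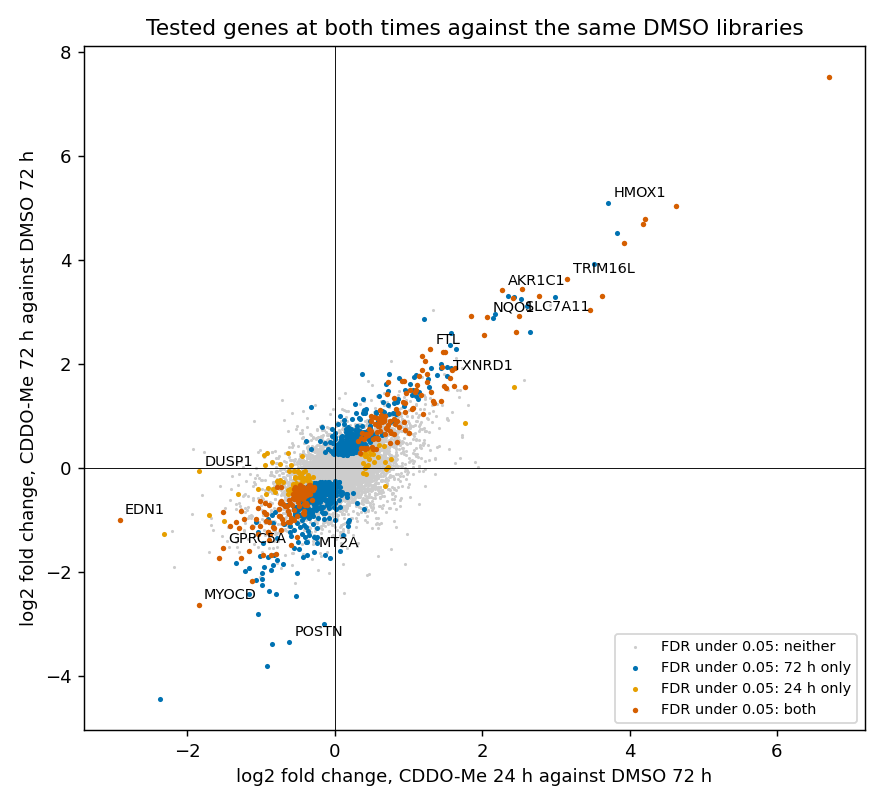
Log2 fold change of each tested gene at 24 h (x axis) and 72 h (y axis) against the same DMSO libraries; colours show in which comparison the adjusted p was under 0.05, and the shared controls alone give a positive slope. NQO1 lies at 2.06 and 2.90, EDN1 at −2.92 on the x axis, and POSTN at −3.33 on the y axis.

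Between 24 h and 72 h of treatment, EDN1, DUSP1, JUN and CCN1, which were lower at 24 h than in DMSO, were higher at 72 h than at 24 h, and POSTN and the metallothionein genes MT2A and MT1E were lower. EDN1 rose by 1.92 ± 0.24, from 5.17 ± 0.539 to 19.6 ± 1.02 CPM (adjusted p 0.00319), DUSP1 by 1.79 ± 0.16, RHOB, a small GTPase gene, by 1.49 ± 0.11 and the transcription factor genes KLF6 by 1.20 ± 0.15 and ATF3 by 1.00 ± 0.16. RHOB and ATF3 had not passed at 24 h against DMSO (adjusted p 0.187 and 0.0915). DUSP8 was at 1.21 ± 0.20 (0.00979; up to 0.0673 without CDDO-Me 24 h replicate 2 or any 1 of the 72 h libraries). POSTN was lower by −2.71 ± 0.18 (8.96e-06), MT2A by −1.33 ± 0.10 and BHLHE40 by −1.20 ± 0.16. CDCP1 (−1.22 ± 0.24, 0.0332), TXNIP (−1.18 ± 0.19, 0.0223) and MLPH (−1.09 ± 0.18, 0.0150) were lost without CDDO-Me 24 h replicate 2 or any 1 of the 72 h libraries, and the first 2 also without CDDO-Me 24 h replicate 1 (up to 0.186, 0.139 and 0.0893). CDCP1 was lost without DMSO replicate 3 too. In the immediate early list 5 of 15 rose (11 adjusted over the list alone; median 0.82, camera 5.85e-20, adjusted p 0.0521 with an estimated correlation), with DUSP1, ATF3 and JUN (0.82 ± 0.11). Without DMSO replicate 1 there were 8, and 3 without CDDO-Me 24 h replicate 2 or any 1 of the 72 h libraries. In the TGF-beta and YAP list CCN1 rose (0.99 ± 0.08) and TGFBI was lower (−0.93 ± 0.14; 0.0547 without CDDO-Me 72 h replicate 1), and adjusted over the list alone 3 rose and 2 were lower. The list's median was −0.01 and its mean 0.10 with all libraries (camera 0.0927). Without CDDO-Me 24 h replicate 3, 5 rose and 2 were lower.

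Of the 49 NRF2 targets, 6 were higher at 72 h than at 24 h (18 adjusted over the list alone; median 0.30, camera 5.85e-20, adjusted p 0.0896 with an estimated correlation). They included NQO1 (0.83 ± 0.10), EPHX1 (0.69 ± 0.09) and FTL (0.99 ± 0.14). HMOX1, GCLM, TXNRD1 and SRXN1 did not pass (1.38, 0.42, 0.24 and 0.20; adjusted p 0.399, 0.621, 0.821 and 0.880), and without CDDO-Me 24 h replicate 3 they did (2.49, 0.93, 0.81 and 0.88; 1.98e-12, 6.24e-08, 2.20e-05 and 0.0121), with 31 NRF2 targets higher and 1 lower. Without CDDO-Me 72 h replicate 3, 3 were higher. Metallothioneins MT2A and MT1E (−0.69 ± 0.10) were the 2 of 5 that were lower (2 adjusted over the list alone; list median −0.69, camera 6.89e-11, adjusted p 0.0169 with an estimated correlation). In the extracellular matrix list 2 of 23 were lower (7 adjusted over the list alone; median −0.31, camera 3.71e-07, adjusted p 0.257 with an estimated correlation), and the list's call ended with the retained-RNA score as a covariate (adjusted p 0.525). Its count was 13 without CDDO-Me 24 h replicate 3, 1 without DMSO replicate 3, and 0 without DMSO replicate 2, CDDO-Me 24 h replicates 1 or 2 or any 1 of the 72 h libraries (by edgeR with all libraries 10 were lower at an unadjusted p under 0.05, by DESeq2 5 and by limma-voom 2). Of 11 fibroblast markers POSTN was lower (3 lower adjusted over the list alone; median −0.17, camera 3.97e-06, adjusted p 0.157 with an estimated correlation), and 5 were lower and 1 higher without CDDO-Me 24 h replicate 3. Of all genes 67 were higher and 85 lower. The total of 152 was 242 and 98 without DMSO replicates 1 and 2, 78, 56 and 1843 without CDDO-Me 24 h replicates 1, 2 and 3, 33, 39 and 32 without CDDO-Me 72 h replicates 1, 2 and 3, 3471 without both libraries that stood apart, and 29 with the retained-RNA score as a covariate. Of 432 genes higher at 72 h than in DMSO, 36 were also higher at 72 h than at 24 h by the direct test, and of 469 lower, 62 were lower and 2 higher. Of 176 genes lower at 24 h than in DMSO, 17 were higher and 7 lower at 72 h than at 24 h, and of 145 higher at 24 h, 11 were higher and 6 lower. These counts test genes again on the same treated libraries that picked them. A gene low by chance in the 24 h libraries would tend to come out higher at 72 h than at 24 h. The same limit applies to EDN1, DUSP1, JUN and CCN1.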

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

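The tests of a 72 h library under a 24 h label, of a mixture of RNA, of gene length for the retained-RNA score and of culture time were chosen only after the result was seen, as were the settings that use the retained-RNA score or leave out both libraries that stood apart. Each value here is listed because treated libraries of 72 h and 24 h differed by the direct test (edgeR for genes, camera for lists; log2 fold changes, 3 libraries a group). With no vehicle library of 24 h analysed, such a difference holds any effect of culture time as well as one of CDDO-Me. It passed for 36 named genes, 19 higher and 17 lower at 72 h, and for 21 lists, 11 higher and 10 lower.

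Of signalling and stress genes, EDN1 was higher by 1.92, DUSP1 by 1.79, RHOB by 1.49, DUSP8 by 1.21, KLF6 by 1.20, ATF3 by 1.00, KLF2 by 0.97, JUN by 0.82, CRYAB by 1.35 and DNAJB4 by 0.51. Among NRF2 targets FTL was higher by 0.99, NQO1 by 0.83, GSTM3 by 0.70, EPHX1 by 0.69 and AKR1B1 by 0.51. CCN1 was higher by 0.99, CNN1 by 0.69, TP53I3 by 0.59 and CDKN1A by 0.54. Lower at 72 h were the matrix genes POSTN (−2.71), TGFBI (−0.93), FN1 (−0.74) and COL6A2 (−0.56), the metallothioneins MT2A (−1.33) and MT1E (−0.69), and the keratins KRT19 (−0.89) and KRT18 (−0.56). The sterol genes INSIG1 (−0.96) and HMGCS1 (−0.44) were lower, as were CDCP1 (−1.22), BHLHE40 (−1.20), TXNIP (−1.18), MLPH (−1.09), ICAM1 (−0.72), SLC7A5 (−0.47) and SLC2A1 (−0.39). With 1 library left out, 20 of the 36 calls were lost at least at 1 library, and 16 held at each.

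List medians were higher for all NRF2 targets (0.30), detoxification (0.69), heme and iron (0.47), NADPH (0.30), glutathione (0.25), immediate early genes (0.82), AHR targets (0.23), heat shock (0.21), nuclear genes of oxidative phosphorylation (0.12), p53 targets (0.11) and the proteasome (0.06). They were lower for metallothioneins (−0.69), endothelial markers (−0.51), fatty acid synthesis (−0.48), extracellular matrix (−0.31), epithelial markers (−0.28), hypoxia and glycolysis (−0.27), NF-kappaB (−0.23), cholesterol synthesis (−0.18), fibroblast markers (−0.17) and ATF4 targets (−0.16). With an estimated correlation 1 list kept its call, metallothioneins. In 16 of the 21 lists over 1.5 times more members passed without CDDO-Me 24 h replicate 3. In 5 lists no member passed by edgeR: fatty acid synthesis, endothelial markers, oxidative phosphorylation, the proteasome and AHR targets. At an unadjusted p under 0.05, 8, 2, 3, 0 and 1 members of these passed, 2, 0, 0, 0 and 1 by DESeq2 and 0 of each by limma-voom, and without CDDO-Me 24 h replicate 3 these counts were 9, 1, 0, 5 and 2 by edgeR (AHR targets 1 without DMSO replicate 1). The proteasome list turned direction, without passing, with the retained-RNA score (adjusted p 0.525) or the library split (0.608) as a term, and its call ended without CDDO-Me 24 h replicates 1 (0.479) or 2 (0.346). The calls of other lists ended with 1 library left out too: endothelial markers without CDDO-Me 24 h replicate 3 (0.182) or CDDO-Me 72 h replicate 1 (0.0521), AHR targets without CDDO-Me 24 h replicate 2 (0.0792), and NF-kappaB without CDDO-Me 24 h replicate 1 (0.164) or CDDO-Me 72 h replicate 3 (0.0501). With the retained-RNA score as a covariate, the camera calls of glutathione (adjusted p 0.525), extracellular matrix (0.525), cholesterol synthesis (0.789) and AHR targets (0.789) ended. So did those of NF-kappaB (0.316), p53 targets (0.0563) and oxidative phosphorylation (0.0602). Of fatty acid synthesis genes 1 of 11 passed without DMSO replicate 1, and the list's call ended with that covariate too (0.182). That list's median, relative to the DMSO mean, was 0.44 and 0.36 in CDDO-Me 24 h replicates 1 and 2, −0.32 in replicate 3 and −0.29 to −0.36 at 72 h. Of hypoxia and glycolysis genes 1 of 19 passed, 12 without CDDO-Me 24 h replicate 3, and 0 without DMSO replicate 2, CDDO-Me 24 h replicates 1 or 2 or any 1 of the 72 h libraries (7 lower at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom). Its median was 0.32 and 0.28 in replicates 1 and 2, −0.09 in replicate 3 and −0.10 to 0.01 at 72 h.

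The NRF2 target list was higher in CDDO-Me 24 h replicate 3 (median 0.99) than in replicates 1 and 2 (0.60 and 0.67). Against a 72 h library under a 24 h label stood the immediate early median of replicate 3, at −0.70 from the lowest 72 h library. In that list the DMSO libraries alone ran from −0.27 to 0.18. Other lists were divided. The extracellular matrix median of replicate 3 (−0.40) lay near the 72 h libraries (−0.34 to −0.36), not replicates 1 and 2 (0.15 and 0.11). Its metallothionein median (−0.24) lay nearer to replicates 1 and 2 (−0.07 and 0.07) than to the 72 h libraries (−0.58 to −1). By coefficient of variation replicate 3 lay nearer to the 72 h libraries (12.8 to 13.5%) than to replicates 1 and 2 (19.9 and 20.9%). Pairs of 72 h libraries differed by only 2.7 to 3.3%, which argues against replicate 3 being 1 more library of that set. A wrong label on a 72 h library handled apart from that set stays open. A mixture of 24 h and 72 h RNA is argued against, since replicate 3 lay outside the range of the other 5 CDDO-Me libraries in 9.84% of 9776 genes, and no other of these libraries did in more than 2.59%. Gene length is argued against, since the fitted length trend put the list's genes at −0.02 in replicate 3 against replicates 1 and 2, and at no more than 0.05 in size, where the difference was 0.32 (0.34 with the trends removed, which moved genes by a median of 0.012 and is by itself a weak test). The labels name nothing that sets this sample apart, so no biological explanation was tested, and a difference in culture, handling or RNA quality stays open, where the RNA quality list's median was −0.47 in replicate 3 and 0.61 and 0.44 in replicates 1 and 2.

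The retained-RNA score was higher in DMSO replicate 1 (0.20) and CDDO-Me 24 h replicates 1 (0.14) and 2 (0.38) than in the other 6 libraries. Gene length is argued against, since its Spearman correlation with the difference, across genes, was −0.064 in the DMSO group and 0.079 in the 24 h group. RNA that keeps introns, counted in exons annotated as retained introns, stays open: the correlation with the share of such exons was 0.085 and 0.078, between the bounds set for either reading, and genes are not independent replicates. Both groups hold libraries on either side, so no biological explanation that the design names was tested.

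The immediate early list was lower at 24 h than in DMSO (median −0.62) and higher at 72 h than at 24 h (0.82, adjusted p 0.0521 with an estimated correlation, where the call of this second part ended). Both parts rest on the same 24 h libraries, so they are not independent. DMSO replicate 1, with a high retained-RNA score, was low in the list too (−0.27, against 0.12 and 0.18 in the other DMSO libraries). The retained-RNA content of the libraries is argued against as the whole cause, since the list passed in the same direction with that score as a covariate, at 24 h against DMSO (camera, adjusted p 1.7e-11; up to 0.0467 over the alternatives) and at 72 h against 24 h (2.11e-08; up to 0.0521), both highest with an estimated correlation. An effect of culture time cannot be told apart from one of CDDO-Me, since no vehicle library of 24 h was analysed, and at the matched time of 72 h the median was −0.06. An early response to CDDO-Me that passes by 72 h may account for the pattern too, a hypothesis not tested here, which vehicle libraries of 24 h would test, as they would be as low as the treated ones under culture time alone.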

How the results depend on the processing

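The settings that leave out both libraries that stood apart (DMSO replicate 1 and CDDO-Me 24 h replicate 3), leave out libraries of the third group, use the retained-RNA score or a split of the libraries on it as a term, weight samples or remove length trends were chosen after seeing the data. The causes of the changes below were not tested. A fit of 2 groups, or one that leaves out libraries, has fewer libraries, which alone cannot account for every rise. At 72 h against DMSO the 24 h libraries enter only through the filter, the library size factors and the pooled spread. In that comparison 933, 805 and 1972 genes passed without CDDO-Me 24 h replicates 1, 2 and 3, against 901 with all libraries. With 2 libraries left in a group, the spread is pooled over all groups. At 24 h against DMSO 321 genes passed, and 134 to 1657 with 1 library left out, the last without CDDO-Me 24 h replicate 3, where 317 of the 321 were among them. The total was 662 with no filter, 546 by DESeq2, 100 with 2 groups only, 3464 without both libraries, 560 with the library split and 1656 with sample weights. Of these, 74 were at least 2-fold, and 51 to 197 with 1 library left out. With no filter 128 were, 46 with 2 groups only, 384 without both libraries, 120 with the split and 195 with weights. At 72 h against DMSO 901 passed, and 401 to 1972 with 1 library left out, 1776 with 2 groups only, 2724 without both libraries and 2593 with weights. At least 2-fold were 221, and 147 to 314 with 1 library left out, and 347 with weights. At 72 h against 24 h 152 passed, and 32 to 1843 with 1 library left out, 507 with no filter, 388 by DESeq2, 3471 without both libraries, 29 with the retained-RNA covariate and 2918 with weights. At least 2-fold were 23, and 10 to 303 with 1 library left out. With no filter 73 were, 51 by DESeq2, 445 without both libraries, 7 with the covariate and 391 with weights.

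Of 39 lists other than all NRF2 targets, camera called 19, 24 and 20 in the comparisons of 24 h with DMSO, 72 h with DMSO and 72 h with 24 h. With an estimated correlation it called 10, 10 and 1, where the NRF2 target list at 72 h against 24 h had an adjusted p of 0.0896. At 72 h against 24 h fry called 13. With the retained-RNA covariate 12 were called in that comparison, among them the interferon list, which had not passed in the main fit. Some lists that camera had not called in the main fit turned direction and passed. Without both libraries that stood apart, the extracellular matrix list at 24 h against DMSO turned from lower to higher (adjusted p 0.000156, from 0.325). The RNA quality list at 72 h against 24 h turned too (0.00962, from 0.607). At 72 h against 24 h the interferon list (0.781 in the main fit) turned direction with the covariate (0.00614) and with the library split (0.0155). The proteasome list, called in the main fit (0.0228), turned without passing (0.525 and 0.608). The overlap of calls at both times was 241, and 104 to 615 with 1 library left out, 365 by DESeq2, 1196 without both libraries (96 genes in opposite directions), 383 with the library split and 58 at least 2-fold at both times.

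Counting each list other than all NRF2 targets once per alternative, direction and call were kept 745 times at 24 h against DMSO, the list passed newly 30 times, no longer passed 42 times and turned 1 time. At 72 h against DMSO these were 768, 9, 41 and 0, and at 72 h against 24 h 733, 29, 51 and 5. Counting each of 75 named genes once per alternative, direction and call were kept 1489 times, the gene passed newly 47 times and no longer passed 114 times at 24 h against DMSO. For 96 genes at 72 h these were 1862, 23 and 227 times, and for 62 at 72 h against 24 h 1173, 44 and 147. With 1 library left out in turn, 33 of 51 named calls held each time at 24 h against DMSO, 53 of 86 at 72 h and 16 of 36 at 72 h against 24 h. Replicate numbers showed at most a weak pairing, with correlations of deviations from −0.028 to 0.082 for equal numbers and −0.109 to 0.04 for unequal ones. With the number as a block 358, 963 and 219 genes passed (321, 901 and 152 with no block), and 19, 23 and 22 lists. At both times 258 genes passed, 2 in opposite directions. At this depth a count of 0 allows a level of up to 3 counts, 0.107 to 0.178 CPM.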

Other observations

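The settings that leave out both libraries that stood apart, use the library split, weight samples or use the retained-RNA score were chosen only after the result was seen. AC16 cells carried little RNA of the contractile apparatus of heart muscle. Of 29 cardiomyocyte markers 5 were tested. Another 11 had no count in any of the 9 libraries, among them the myosin genes MYH6, MYH7 and MYL2 and the calcium release channel gene RYR2. For each library taken alone this allows up to 0.107 to 0.178 CPM, and for the 9 together less. The remaining 13 were counted but too low to test, with troponin T (TNNT2) at no more than 5 counts and cardiac actin (ACTC1) at no more than 19 counts (0.918 CPM). Of those tested, the calcium pump gene ATP2A2 reached 655 CPM, the connexin gene GJA1 243, the transcription factor gene GATA4 26, the titin gene TTN 8.88 and desmin (DES) 2.37. GJA1, 1 of these 5, was lower at 72 h than in DMSO (−0.86, adjusted p 0.00258 by edgeR; list 0.0433 by camera, adjusted p 0.131 with an estimated correlation). No mitochondrial gene was in the table, so none of 13 mitochondrial genes was measured.

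Of 20 G2/M and 20 S phase genes edgeR, DESeq2 and limma-voom called 0 at 24 h or 72 h against DMSO. At an unadjusted p under 0.05, 0 of either list were called at 24 h, and 1 G2/M gene higher, 2 S phase genes higher and 1 lower at 72 h. Without CDDO-Me 24 h replicate 3, 3 G2/M genes and 1 S phase gene were lower at 24 h, and 1 of each was lower and 1 G2/M gene higher at 72 h. Without DMSO replicate 3, 1 G2/M gene was higher at 72 h. In the ferroptosis list AIFM2, which encodes a suppressor of ferroptosis, rose at 24 h (0.58, adjusted p 0.00626) and 72 h (0.68, 0.000714). TFRC, the transferrin receptor gene, rose at 24 h too (0.36, 0.0374; up to 0.147 with 1 library left out) and was among the members higher at 72 h. Of 12 members tested 2 were higher at 24 h and 3 at 72 h, and adjusted over the list alone 3 were higher and 1 lower, and 3 higher and 3 lower. At 24 h the count was 1 without DMSO replicate 2, CDDO-Me 24 h replicate 2 or any 1 of the 72 h libraries, and 4 higher and 2 lower without CDDO-Me 24 h replicate 3. At 72 h it was 1 without DMSO replicates 1 or 2 or any 1 of the 72 h libraries. In that comparison 1 was lower without CDDO-Me 24 h replicate 1, and 3 were without replicate 3. The ferroptosis list did not pass by camera (adjusted p 0.0542 and 0.193), except at 24 h without DMSO replicate 3 (0.0283), with no filter (0.0345), with the retained-RNA score (0.0272) or with the library split (0.0374), and it passed by fry (0.00443 and 0.00905). In the autophagy and lysosome list 2 of 18 rose at 24 h and 3 at 72 h (3 and 3 adjusted over the list alone, 5 and 5 without CDDO-Me 24 h replicate 3). At 24 h the count was 1 without DMSO replicates 2 or 3 or any 1 of the 72 h libraries. The cathepsin gene CTSL rose at 24 h (1.05, 0.00121) and 72 h (1.13, 0.000295), where the list's adjusted p was 0.00029 and 0.0114, and 0.0534 and 0.131 with an estimated correlation. TEK, an endothelial receptor gene and 1 of 6 endothelial markers, was lower at 72 h (−0.83, 0.00267; list 0.0323, adjusted p 0.131 with an estimated correlation). The interferon list had 3 genes lower at 72 h by edgeR (4 lower and 1 higher adjusted over the list alone; camera, adjusted p 0.477). Without DMSO replicate 1, 1 was lower, and without DMSO replicates 2 or 3 or any 1 of the 72 h libraries 0 were (with all libraries 4 were lower and 2 higher at an unadjusted p under 0.05, 4 lower and 1 higher by DESeq2, and 2 lower by limma-voom). There were 4 lower and 3 higher without CDDO-Me 24 h replicate 3.

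Splits of the 6 libraries of a comparison were tested in the same way, and 10 splits cannot give a share under 0.1. For 24 h against DMSO the real split called 321 genes and 2 of 10 splits called as many. The highest other, 748, set DMSO replicate 1 and CDDO-Me 24 h replicates 1 and 2 against the rest. That count points to a structure of the samples, and with this split as a term 560 genes passed. Both groups shared it only weakly, as their differences across the split correlated at 0.126 (Spearman, 9776 genes). How much each group adds to the 748 calls was not tested. For 72 h against DMSO the real split called 901 and the highest other 0 (1 of 10 splits as large), and for 72 h against 24 h 152 and 0 (1 of 10).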
